A study of Homo sapiens with 4 samples.

How the data were processed

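RNA of T98G glioblastoma cells was measured on 4 Affymetrix Human Genome U133 Plus 2.0 arrays, 1 each for cycling cells, cells in G0 after 72 h without serum, and serum-restimulated cells labelled as G1 and S phase. Per the labels' protocols, total RNA was extracted with Trizol and purified on columns, and 15 µg were used for biotin-labelled cRNA. Restimulation times of 10 h and 16 h are named there without being assigned to the G1 or the S label. Cell cycle position was checked by BrdU labelling and flow cytometry per the series description, and those measurements were not analysed here.

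The deposited values are MAS5 signals on a linear scale, per the submitters' processing notes. The software version, the scaling target and the detection calls are not given in the sources used here. The 2% trimmed means of the deposited signals were 55.5, 47.6, 39.4 and 45.7 on the cycling, G0, G1 and S arrays. These means alone do not show whether the arrays differed in scale or in RNA content. Of 54675 probe sets, 62 were Affymetrix controls. Of the other 54613, 41097 carried 1 gene symbol in the platform annotation, 1801 several and 11715 none, and only those with 1 symbol were used. Of these, 41043 were matched by Entrez identifier to the RefSeq gene table of assembly GRCh38.p14, which was used for names alone, and 0 symbols needed updating. They gave 19775 genes, 10523 of them with several probe sets.

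Each array was multiplied by a factor (0.848, 0.988, 1.19 and 1.03) that gave all arrays the same 2% trimmed mean over the probe sets that are not controls. Signals below the median of all scaled signals, 18.3, were set to that floor, and log2 ratios were taken. Each gene was represented by the probe set with the highest mean signal over the 4 arrays, a rule that does not look at differences. A gene counted as measured when above the floor on at least 1 of the 2 arrays compared. It counted as higher or lower from 2-fold. Where the dimmer signal was at the floor the fold is a lower bound, which held for 1195 of the higher and 421 of the lower genes of G0 over cycling. The arrays were grouped by their labels. Main comparisons were G0 over cycling, G1 over G0, S over G1 and S over G0, and secondary ones were G1 and S over cycling. With 1 array per group no test, p-value, standard error, replicate left out or split of the samples was possible, and the number of arrays limits the precision.

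A total of 30 gene lists were fixed: origin licensing and firing, replication fork, nucleotide synthesis, G1/S regulators, G2 and mitosis, replication-dependent histones, DNA repair, quiescence and arrest, the MuvB (DREAM) core, immediate early genes, SRF and YAP targets, cholesterol and fatty acid synthesis, ribosome assembly, ribosomal proteins, proteasome, glycolysis and hypoxia, oxidative phosphorylation, amino acid and ER stress, lysosome and autophagy, interferon response, NF-kappaB and cytokines, extracellular matrix, p53 targets, glial, neuronal, epithelial and haematopoietic markers, reference genes and 15 key genes. The list named MuvB (DREAM) core, called the DREAM list below, also held DREAM members outside MuvB, among them RBL2, TFDP1 and TFDP2. Of 763 members, 702 were matched to a gene. For each list the median log2 ratio of its measured members was placed among the medians of 10000 random lists of the same size, drawn in 20 bins of mean expression. The percentile describes these arrays and is not a test. The matched random lists placed 79 of 173 list medians outside the middle 95%. Unmatched random lists placed 64 outside, 61 of them also outside with matching and on the same side.

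The named genes were the 10 largest log2 ratios in each direction per main comparison (5 in secondary ones) among genes changed at least 2-fold, with a brighter signal of at least 4 floors (73.3) and no other measured probe set of opposite sign. To these came the 15 key genes and up to 4 members of each list with the largest ratios. List members named as the few going against their list, or to list all members behind a small count, were chosen after their values were seen. The groups, lists, comparisons, named-gene rule and alternatives were chosen before the data were examined, except for the probe sets used to fit the loess. The alternatives were the signals as deposited, quantile normalisation, scaling by the 75th percentile, a loess of log2 ratio on mean log2 signal (span 0.3), a floor at the 25th or 75th percentile, the floor as a pseudocount, the mean over probe sets, leaving out probe sets with _x_at and _s_at endings, thresholds of 1.5-fold and 3-fold, and support from a second probe set. The loess was first fitted to probe sets above the floor. After its first counts were seen it was fitted to all probe sets that are not controls. The first fit was run again, for the counts and the histone list, as an alternative added after the data were seen.

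Precision was judged from genes with several probe sets. Between probe sets of a gene the log2 ratios had an SD per probe set of 0.69 for G0 over cycling, 0.73 for G1 over G0, 0.61 for S over G1 and 0.72 for S over G0. The 18 probe sets of the hybridisation controls had an SD of their log2 ratios between 0.09 and 0.14 over the 6 comparisons. Their means were 0.08, -0.19, 0.02, -0.17, -0.11 and -0.09 as deposited and 0.30, 0.08, -0.19, -0.11, 0.38 and 0.19 after scaling, for G0 over cycling, G1 over G0, S over G1, S over G0, G1 over cycling and S over cycling in that order. The 24 poly-A controls had median scaled signals of 3.71, 2.18, 2.81 and 5.46 on the cycling, G0, G1 and S arrays, all below the floor. The calculation was tested on simulated data with 200 of 19775 genes changed 4-fold and noise of 0.3 log2. The changed genes were drawn only from bright ones, whose mean signal divided by 4 was still above 4 floors. Recovery of dimmer genes was thus not tested. For G0 over cycling the calculation recovered 100% of changed genes and called 0.055% of unchanged ones, and for G1 over G0 99.5% and 0.079%. This noise is lower than the SD per probe set. With noise of 0.7 log2, between 89.5% and 91.5% of changed genes were recovered and between 12.2% and 13.5% of unchanged ones called over the 6 comparisons. With the noise set to the SD per probe set of each comparison and no gene changed, in arrays simulated from each of the 2 arrays in turn, the share past 2-fold was averaged over both. This check and the noise of 0.7 were added after the data were seen. Of simulated lists without a shift, 5% to 8% lay outside the middle 95% of matched random lists. Those lists were drawn at random with independent noise, so a share near 5% follows by construction. It does not show how often lists of co-regulated genes lie outside. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and figures matplotlib 3.10.9.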

Results

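Gene expression was measured in T98G, an established human glioblastoma cell line that stops dividing when serum is withdrawn, with 1 Affymetrix Human Genome U133 Plus 2.0 array for each of 4 conditions. The cultures were cycling, arrested in G0 by 72 h without serum, or restimulated with serum and labelled as G1 or S phase. The growth protocol names release times of 10 h and 16 h, without stating which of them belongs to the G1 or the S label. With 1 array per condition there were no replicates, so no test, standard error or p-value could be given, and the number of arrays limits the precision of each comparison. Values are MAS5 signals scaled to a common trimmed mean. A gene was counted as higher or lower when its signals differed at least 2-fold after dim signals were raised to a floor of 18.3, and "at least" marks a fold whose dimmer signal lay at that floor. Different probe sets of 1 gene gave the only internal measure of error for genes, beside the hybridisation controls with an SD of 0.09 to 0.14 log2. Where the main probe set of a gene differed at least 2-fold, the direction was shared by 67.3% of the other probe sets for G0 over cycling, 71.3% for G1 over G0, 66.8% for S over G1 and 67.3% for S over G0. A difference of at least 2-fold in that direction was found for 23.8%, 30.5%, 21.4% and 26.2% of them, and the log2 ratios of the main and the other probe sets had correlations of 0.28, 0.37, 0.25 and 0.29 over all pairs. On simulated arrays without change, with noise equal to the SD between probe sets of a gene, 12.2%, 14.5%, 8.33% and 14.4% of genes lay past 2-fold. The measured shares in these comparisons were 23.2%, 27.7%, 15.6% and 25.1%. That SD sets the brightest probe set of a gene against its dimmer ones and holds no spread between cultures. The simulated shares are thus a rough guide and not an error rate of the counted genes.

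Between 12035 genes (G1 array) and 13384 genes (G0 array) lay above the floor, with 12043 on the cycling and 12473 on the S array. The median scaled signal was 22.6 on the G0 array, against 16.8 on the cycling, 16.9 on the G1 and 18.2 on the S array. The 3' to 5' signal ratio of the ACTB control was 15.5, 17.6, 13.4 and 12.3 on the cycling, G0, G1 and S arrays. The ratio of the GAPDH control was 7.01 on the G1 array and 4.47, 3.85 and 3.44 on the cycling, G0 and S arrays. Both controls thus had 3' signals at least 3.44 times their 5' signals on every array, and not on the G1 array alone. This ratio follows RNA integrity and labelling, and its effect on the comparisons was not tested. Of the 13 epithelial markers on the array, 6 were above the floor on the G0 or the cycling array, and 9 of 13 haematopoietic and 8 of 12 neuronal markers were. The haematopoietic markers at least 2-fold higher on the G0 than the cycling array were CD3D, CD3E and CD4, with G0 signals of 41.6, 50.1 and 45.3. Their cycling signals of 10.3, 11.6 and 12.9 lay below the floor, so these folds are lower bounds. Without detection calls, a signal above the floor does not show that a gene was expressed.

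The comparison of G0 with cycling cells asked which genes differ when serum withdrawal stops the cell cycle. Genes of DNA replication and mitosis were lower on the G0 array. RRM2, the small subunit of ribonucleotide reductase, gave a signal of 342 against 1829 (5.34-fold lower), and PCNA, the sliding clamp of the replication fork, 419 against 1425 (3.40-fold lower). The mitotic kinase CDK1 and its partners cyclin A2 and cyclin B1 were 3.24-fold, 2.95-fold and 2.39-fold lower, and the transcription factor MYC was 4.15-fold lower. Of 15135 genes above the floor on at least 1 of the arrays, 2222 were at least 2-fold higher in G0 and 1284 at least 2-fold lower.

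The lists of replication, division and ribosome assembly genes lay lower in G0. Of 20 factors of origin licensing and firing, 15 were at least 2-fold lower and 0 higher (median log2 ratio -1.22), among them MCM10 (at least 7.09-fold lower), the licensing inhibitor geminin, GMNN (4.43-fold), and CDC6 (3.80-fold). Of 52 G2 and mitosis genes, 36 were lower and 1 higher, the centromeric histone variant CENPA (median -1.26). KIF23, a kinesin of cytokinesis, was at least 6.51-fold lower, the kinetochore motor CENPE at least 6.23-fold lower and DLGAP5 5.80-fold lower. Lower signals were also found for 17 of 31 replication fork genes (median -1.17) and 8 of 14 nucleotide synthesis enzymes (median -1.41). Thymidylate synthase, TYMS, was 4.53-fold lower. The same held for 8 of 14 repair and checkpoint genes (median -1.21), including the recombination factor RAD51AP1 (4.23-fold lower), and 7 of 19 G1/S regulators (median -0.82), including cyclin E2 (3.03-fold lower) and the kinase CDK2 (3.05-fold lower). Cyclin D1 was at 86.0 against 83.9, and its probe sets differed in sign. Of 28 ribosome assembly factors, 9 were lower (median -0.80), LYAR by 4.61-fold. The medians of these 7 lists lay below the middle 95% of random lists matched on expression in the main setting and in each of 9 alternatives.

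The medians of the lysosome, cholesterol synthesis and matrix lists were higher in G0. The 10 genes with the largest ratios included CBLN2 (at least 13.2-fold), the complement component C3 (9.26-fold), the selenium carrier SELENOP (8.54-fold), the matrix calcification inhibitor MGP (at least 7.54-fold) and the transmembrane glycoprotein GPNMB (859 against 118, 7.26-fold). Of 28 lysosome and autophagy genes, 10 were higher and 1, the cholesterol exporter NPC1, was lower (median 0.42). The higher genes included PSAP, the precursor of the saposins (3.16-fold), the sterol carrier NPC2 (3.06-fold) and the autophagy gene GABARAPL1 (3.28-fold). Of 18 cholesterol synthesis genes, 5 were higher and 0 lower (median 0.62), among them MSMO1 (3.16-fold) and HMGCS1 (2.57-fold). Of 35 matrix genes, 10 were higher and 5 lower (median 0.43). Among random lists not matched on expression, the lysosome and matrix medians lay at percentiles 94.8 and 96.8. Periostin, POSTN, was at least 4.76-fold higher and the matrix protease MMP3 6.13-fold lower. The quiescence and arrest list held 7 higher and 0 lower members of 29, and its median of 0.28 lay at percentile 93.3 of the random lists. Its higher members included the CDK inhibitors CDKN1C (3.79-fold) and CDKN2B (2.82-fold). CDKN1A was at 133 against 73.9 and CDKN1B at 493 against 363. The 3 genes with the largest lower ratios were ID3 (at least 20.3-fold) and ID1 (at least 14.4-fold), inhibitors of bHLH transcription factors, and the Wnt antagonist DKK1 (53.1 against 654, 12.3-fold).

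Of the genes that differed at least 2-fold, 63.4% were higher in G0. That share was 47.4% with the signals as deposited, 50.1% after quantile normalisation and 51.8% after loess fitted to all probe sets. It was 39.8% with each array divided by its 75th percentile and 25.2% with the loess fitted above the floor. The balance of higher against lower genes was thus not settled by these arrays.

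**Figure D1:**
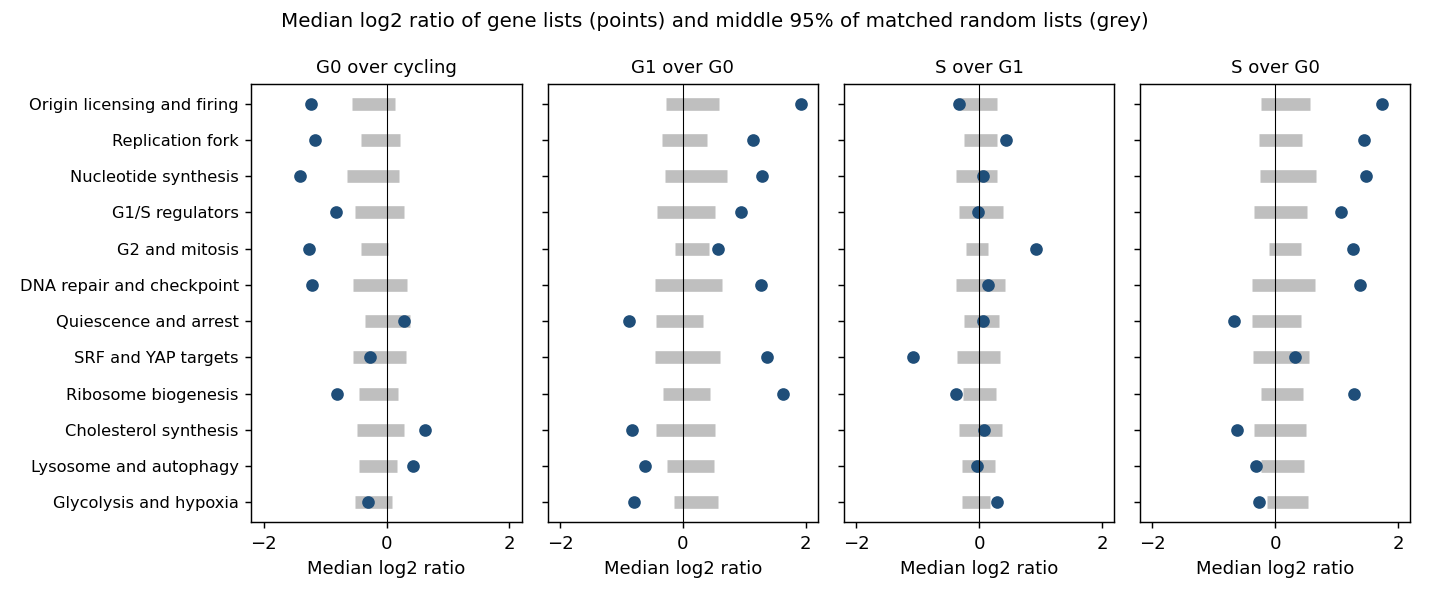
Median log2 ratio (horizontal axis) of 12 gene lists in the 4 main comparisons, 1 panel per comparison, with points for list medians over measured genes and grey bars for the middle 95% of 10000 random lists matched on mean expression. The list of origin licensing and firing factors lies at -1.22 for G0 over cycling, 1.93 for G1 over G0, -0.33 for S over G1 and 1.74 for S over G0.

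The comparison of G1 with G0 addressed the return from quiescence after serum was given back. Genes of origin licensing, ribosome assembly and the SRF and YAP list were higher on the G1 array. DKK1 gave a signal of 3781 against 53.1 (71.3-fold higher), the chemokine CXCL8 was at least 26.0-fold higher, and CCN1, a matricellular target of SRF and YAP, stood at 2289.8 against 142 (16.2-fold). ODC1, the first enzyme of polyamine synthesis, was 12.2-fold higher, and MYC 6.90-fold higher. Of 15174 genes above the floor on at least 1 of the arrays, 1551 were at least 2-fold higher in G1 and 2653 at least 2-fold lower.

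Of the 20 licensing and firing factors, 18 were at least 2-fold higher and 0 lower (median 1.93), among them MCM10 (at least 11.6-fold), CDC6 (7.49-fold) and GMNN (6.01-fold). Of 31 fork genes, 16 were higher, including TIPIN (7.51-fold), the loader subunit RFC5 (5.75-fold) and UHRF1 (5.71-fold), and 1, the polymerase subunit POLD1, was lower (median 1.13). Nucleotide synthesis had 9 of 14 genes higher and 0 lower (median 1.28), with CTP synthase, CTPS1, 6.19-fold higher. The G1/S regulators had 9 of 19 higher and 0 lower (median 0.95). Cyclin E2 was 4.87-fold higher, cyclin D1 3.14-fold and the phosphatase CDC25A 2.97-fold. Repair and checkpoint genes had 8 of 13 higher and 1, ATM, lower (median 1.27). The G2 and mitosis genes were mixed, with 16 of 52 higher and 4 lower (median 0.57). Cyclin A2 was 2.36-fold higher. The 4 lower genes were CENPA (at least 4.47-fold), CCNF, CDC25B and the proliferation antigen MKI67 (2.91-fold), whose probe sets differed in sign.

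Ribosome assembly factors had 18 of 29 members higher and 0 lower (median 1.63), with LYAR 11.6-fold, NOP14 6.29-fold and NOLC1 5.48-fold higher. SRF and YAP targets had 13 of 17 members higher (median 1.36), among them urokinase, PLAU (8.48-fold), and tissue factor, F3 (4.80-fold). The 2 lower members were the smooth muscle genes ACTA2 and MYL9. The immediate early list was split, with 6 of 27 higher and 5 lower (median 0.13, percentile 79.2, and -0.14 with the signals as deposited). FOSL1 was 6.83-fold and the growth factor HBEGF 3.98-fold higher, while JUND was 3.83-fold lower.

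Genes lower in G1 than in G0 included PI15, a secreted inhibitor of trypsin (78.7 against 3481, 44.3-fold), NDRG1 (110.2 against 2284, 20.7-fold) and DDIT4, an inhibitor of mTORC1 signalling (23.8 against 452, 19.0-fold). The quiescence and arrest list had 13 of 29 members lower and 1, the growth arrest gene GAS6, higher (median -0.87). CDKN1A was 6.04-fold lower, CDKN1B 2.54-fold and the transcriptional repressor HBP1 at least 9.96-fold. Cholesterol synthesis had 6 of 17 genes lower and 0 higher (median -0.82), with INSIG1 4.19-fold and MSMO1 4.06-fold lower. Lysosome and autophagy genes had 8 of 27 lower and 1, NPC1, higher (median -0.62). Glycolysis and hypoxia genes had 9 of 28 lower, including the mitophagy receptor BNIP3L (5.14-fold) and the neuronal enolase ENO2 (at least 4.69-fold), and 2, PFKP and ADM, higher (median -0.80). The 3' to 5' ratio of the GAPDH control was 7.01 on the G1 and 3.85 on the G0 array. The medians of the replication, repair, G1/S, mitosis, ribosome assembly, SRF and YAP, quiescence, cholesterol, lysosome and glycolysis lists lay outside the middle 95% of matched random lists in the main setting and in all 9 alternatives.

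Higher genes made up 36.9% of those that differed at least 2-fold between G1 and G0. The share was 21.6% with the signals as deposited, 48.5% after quantile normalisation, 47.2% after loess and 60.4% with each array divided by its 75th percentile. With the loess fitted above the floor it was 71.4%.

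**Figure D2:**
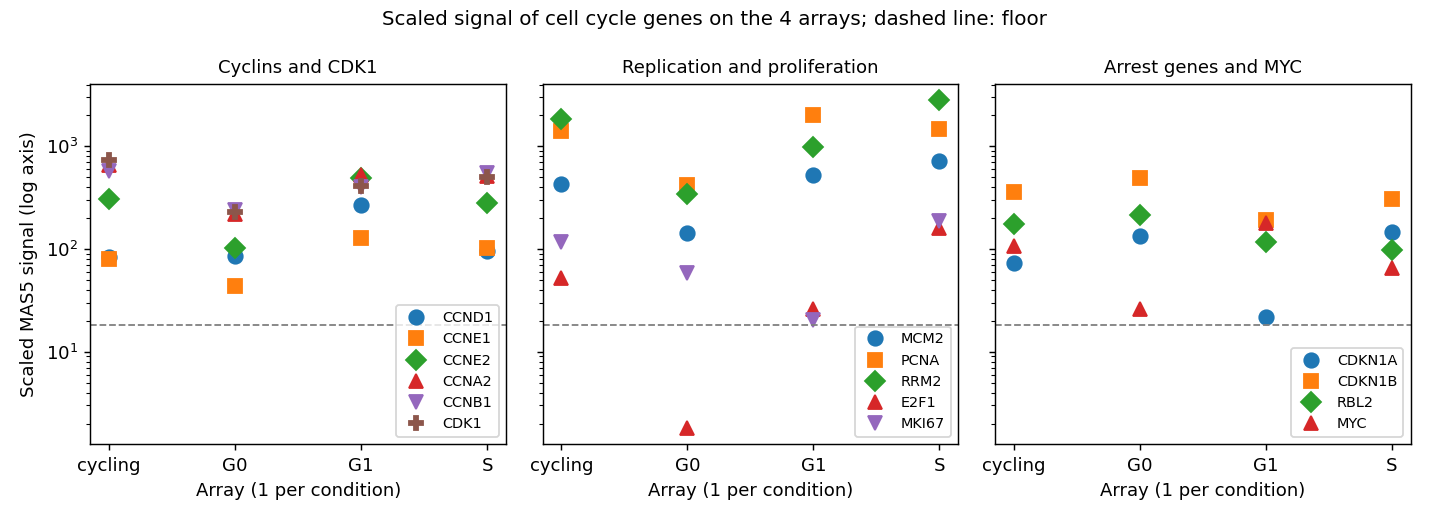
Scaled MAS5 signal (vertical log axis) of 15 genes fixed in advance on the cycling, G0, G1 and S arrays, with 1 point per array and a dashed line at the floor of 18.3, to be compared within a gene and not between genes. MKI67 lies at 116, 58.8, 20.2 and 189, and CDKN1A at 73.9, 133, 22.0 and 146. The probe sets of MKI67 differed in sign for G1 over G0.

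The comparison of S with G1 set the restimulated cells labelled as S phase against those labelled as G1. The list medians of mitosis and replication fork genes were higher on the S array, and those of SRF and YAP targets, cytokine and ribosome assembly genes were lower. MKI67 gave a signal of 189 against 20.2 (9.35-fold higher), the transcription factor E2F1 161 against 25.9 (6.19-fold) and RRM2 2826 against 981 (2.88-fold). The G1 signal of MKI67 lay close to the floor of 18.3, and its probe sets differed in sign for G1 over G0. CXCL8 was 15.2-fold lower, cyclin D1 2.82-fold lower and MYC 2.76-fold lower. Of 14347 genes above the floor on at least 1 of the arrays, 1414 were at least 2-fold higher in S and 817 at least 2-fold lower.

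Among 52 G2 and mitosis genes, 24 were higher and 1, the kinesin KIF18A, was lower (median 0.92). FOXM1, a transcription factor of G2 genes, was 4.39-fold higher, KIF4A 3.81-fold and the mitotic kinase AURKB 3.70-fold. Cyclin A2 was at 520.2 against 522 and CDK1 at 504 against 413. Fork genes had 6 of 31 higher and 1, RFC5, lower (median 0.44), with DNA ligase 1, LIG1, 3.43-fold and the polymerase subunits POLE 3.28-fold and POLD2 2.80-fold higher. The median of the licensing and firing factors was slightly lower in S (-0.33, outside the random range in 6 of 9 alternatives). Of the 20 members, 18 were within 2-fold, 1 was lower and 1 higher. MCM10 was 2.28-fold lower and CDC45 2.02-fold higher. CDKN1A was 6.67-fold higher and PCNA stood at 1489.8 against 2017.

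SRF and YAP targets had 9 of 17 members lower and 1, ACTA2, higher (median -1.08), with F3 10.3-fold, CCN2 at least 7.24-fold and CCN1 4.39-fold lower. Of 16 cytokine and NF-kappaB genes, 6 were lower and 1, ICAM1, higher (median -0.39, 7 of 9 alternatives), including IL6 (at least 5.04-fold) and CCL2 (4.82-fold). Of 27 immediate early genes, 7 were lower and 1, JUND, higher (median -0.31, 7 of 9 alternatives), including the phosphatase DUSP5 (4.22-fold). Ribosome assembly factors had 5 of 29 lower, 3 higher and 21 within 2-fold (median -0.37), with LYAR 2.63-fold lower and RRP9 3.87-fold higher. Matrix genes had 5 of 36 lower (median -0.33), including COL4A1 (3.39-fold), while COL6A2 was at least 12.1-fold higher. Glycolysis and hypoxia genes had 8 of 28 higher and 3 lower (median 0.29, 8 of 9 alternatives), with ALDOA 3.19-fold and ENO2 at least 8.22-fold higher. The median lay at percentile 93.6 of random lists not matched on expression, and the GAPDH 3' to 5' ratio was 3.44 on the S and 7.01 on the G1 array. DDIT4 was 9.57-fold higher. Higher genes made up 63.4% of those that differed at least 2-fold, against 81.0% with the signals as deposited and 52.7% with the 75th percentile. The share was at least 52.7% in the main setting and in each of the 12 alternatives other than the loess fitted above the floor. With that loess, added after the data were seen, it was 29.8%, at an all-gene median of -0.18. The balance thus depended on that fit.

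The comparison of S with G0 set restimulated cells labelled as S phase against quiescent cells. Replication and mitosis genes were higher on the S array. RRM2 gave a signal of 2826 against 342 (8.25-fold higher), MCM2, a subunit of the replicative helicase, 724 against 144 (5.03-fold), and E2F1 was at least 8.77-fold higher. DKK1 was 23.2-fold, ID3 at least 17.4-fold, ID1 at least 14.0-fold and the cohesion factor CDCA5 at least 12.5-fold higher. Of 15412 genes above the floor on at least 1 of the arrays, 1654 were at least 2-fold higher in S and 2220 at least 2-fold lower.

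In 6 lists of replication and division genes no member was at least 2-fold lower in S than in G0. These were the licensing and firing factors (16 of 20 higher, median 1.74), fork genes (24 of 31, median 1.45), nucleotide synthesis (11 of 14, median 1.48), G1/S regulators (10 of 19, median 1.07), G2 and mitosis genes (37 of 52, median 1.26) and repair genes (7 of 13, median 1.37). MCM5 was 8.10-fold higher, the primase-associated polymerase POLA1 6.01-fold, TYMS 6.53-fold, the anaphase activator CDC20 7.22-fold and separase, ESPL1, 7.80-fold. Ribosome assembly factors had 17 of 29 higher (median 1.27). The quiescence list had 9 of 29 lower, including HBP1 (7.80-fold) and BTG1 (3.10-fold), and 3, GAS1, GAS6 and PIK3IP1, higher (median -0.67). CDKN1A stood at 146 against 133. Cholesterol synthesis had 5 of 18 genes lower (median -0.63), with INSIG1 5.29-fold and HMGCS1 3.28-fold lower. Lysosome genes had 4 of 28 lower and 2 higher (median -0.31). These medians lay outside the range of matched random lists in the main setting and in all 9 alternatives, and that of the lysosome list at percentile 12 of unmatched ones.

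Matrix genes had 10 of 37 members lower and 5 higher (median -0.57, 8 of 9 alternatives), with COL3A1 at least 4.30-fold lower and IGFBP3 4.84-fold higher. Other genes lower in S included the decoy receptor TNFRSF11B (9.94-fold), the aldo-keto reductase AKR1B10 (9.65-fold) and NDRG1 (8.86-fold). Among immediate early genes 6 of 28 were lower and 2, FOSL1 (8.37-fold) and MYC (2.5-fold), higher (median -0.54, 6 of 9 alternatives). Higher genes made up 42.7% of those that differed at least 2-fold, and 60.9% with the 75th percentile.

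Set against cycling cells, the G1 array had lower list medians for glycolysis and hypoxia and for mitosis genes, and higher ones for cytokine genes, SRF and YAP targets and ribosome assembly. Of 28 glycolysis and hypoxia genes, 15 were at least 2-fold lower and 0 higher (median -1.06), with BNIP3 at 409.9 against 2346 (5.72-fold lower) and PFKFB3 at 158 against 757 (4.79-fold). On this array the 3' to 5' ratio of the GAPDH control was 7.01, the highest of the 4. Of 52 mitosis genes 17 were lower (median -0.64), MKI67 by 5.77-fold to a G1 signal of 20.2, close to the floor. The stress-inducible gene GADD45A was 9.97-fold higher, follistatin, FST, 9.86-fold and endothelin, EDN1, 9.12-fold. SRF and YAP targets had 6 of 18 higher (median 0.57), ribosome assembly 8 of 29 (median 0.63), cytokine genes 6 of 17 (median 0.50), including CCL2 (4.78-fold), and the licensing and firing factors 2 of 20, MCM6 and CDT1 (median 0.60). Quiescence genes had 7 of 29 lower (median -0.42). Counts were 765 higher and 985 lower of 13967 genes, or 12.5%. Simulated arrays without change gave 5.74% at the probe-set SD of 0.55. At noise of 0.7, which is above that SD, 12.4% of unchanged genes were called. The higher share of 43.7% was 8.25% with the signals as deposited.

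Mitosis genes were at similar levels on the S and the cycling array, with 4 of 52 higher, 1 lower and a median of -0.04. Glycolysis and hypoxia genes had 12 of 28 lower in S than in cycling cells and 1, PFKL, higher (median -0.71). BNIP3 was 4.61-fold, hexokinase 2, HK2, 4.02-fold and the hormone STC1 10.9-fold lower. Fork genes had 3 of 31 higher (median 0.32), including LIG1 (3.43-fold), and MCM5 was 3.70-fold higher. Counts were 1151 higher and 744 lower of 14233 genes, or 13.3%. Simulated arrays without change gave 7.08% at the probe-set SD of 0.58. At noise of 0.7, which is above that SD, 12.9% of unchanged genes were called. The higher share of 60.7% was 31% with the signals as deposited.

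The reference genes often used for normalisation had medians of -0.15 for G0 over cycling, -0.06 for G1 over G0, 0.09 for S over G1, 0.17 for S over G0, -0.26 for G1 over cycling and 0.02 for S over cycling. Each of these signs except that of G1 over cycling changed under another scaling. That median lay below the middle 95% of matched random lists, at percentile 1.87 (outside in 6 of 9 alternatives, and percentile 11.4 of unmatched lists), with 13 of 13 members within 2-fold. HPRT1 was the member past 2-fold, in the comparisons with G0 (2.28-fold lower in G0 than in cycling cells). Glial and neural progenitor markers had 2 members higher in G0 than in cycling cells, GFAP and FABP7, and 2 lower, SOX2 and EGFR, of 12 measured (median 0.06). The probe sets of EGFR differed in sign. Medians for G0 over cycling were -0.03 for neuronal, 0.21 for epithelial and 0.46 for haematopoietic markers, at percentiles 26.8, 48 and 63.9 of matched random lists, and the glial and epithelial signs changed with the scaling.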

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

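The settings were planned, but for loess the plan did not say which probe sets to fit, the fit to all probe sets was chosen only after the counts of the fit above the floor were seen, and the latter was added back after the data were seen. Of 144 counts of higher or lower genes under 12 of the alternatives (all but the loess fitted above the floor), 60 stayed within 1.5 times the main count and 84 did not. A higher floor, a higher threshold or a required second probe set leaves fewer genes by construction, and a lower floor or threshold more. The signals as deposited and the 75th percentile differ from the main setting by 1 factor per array, which shifts ratios above the floor alike and so moves counts. For the mean over probe sets and the loess fitted above the floor the cause was not tested. Quantile normalisation, loess fitted to all probe sets, the floor as a pseudocount and leaving out the shared probe sets moved no count past 1.5 times. With the signals as deposited, the counts (higher and lower) were 2040 lower for G0 over cycling, 957 higher for G1 over G0, 439 lower for S over G1, 237 and 2634 for G1 over cycling and 713 and 1588 for S over cycling. With each array divided by its 75th percentile, the counts (higher and lower) were 1334 and 2014 for G0 over cycling, 2442 and 1598 for G1 over G0 and 1457 lower for S over G0. With the floor at the 25th percentile, the counts (higher and lower) were 4447 and 3207 for G0 over cycling, 3505 and 4778 for G1 over G0, 3591 and 2964 for S over G1, 3595 and 4264 for S over G0, 2988 and 3031 for G1 over cycling and 3302 and 2708 for S over cycling. With the floor at the 75th percentile, the counts (higher and lower) were 469 and 690 for G0 over cycling, 955 and 724 for G1 over G0, 482 and 312 for S over G1, 875 and 561 for S over G0, 289 and 331 for G1 over cycling and 378 and 253 for S over cycling. With the mean over all probe sets of a gene, the counts (higher and lower) were 1253 and 699 for G0 over cycling, 925 and 1495 for G1 over G0, 806 and 382 for S over G1, 1006 and 1175 for S over G0, 425 and 465 for G1 over cycling and 652 and 284 for S over cycling. At 1.5-fold, the counts (higher and lower) were 4289 and 2963 for G0 over cycling, 3142 and 4785 for G1 over G0, 3240 and 2357 for S over G1, 3476 and 4217 for S over G0, 2302 and 2564 for G1 over cycling and 2971 and 2253 for S over cycling. At 3-fold, the counts (higher and lower) were 561 and 339 for G0 over cycling, 523 and 753 for G1 over G0, 309 and 146 for S over G1, 497 and 605 for S over G0, 134 and 209 for G1 over cycling and 204 and 129 for S over cycling. With the support of a second probe set required, the counts (higher and lower) were 297 and 192 for G0 over cycling, 278 and 397 for G1 over G0, 174 and 107 for S over G1, 251 and 302 for S over G0, 105 and 117 for G1 over cycling and 108 and 64 for S over cycling. With the loess fitted above the floor, the counts (higher and lower) were 1207 and 3586 for G0 over cycling, 3938 and 1576 for G1 over G0, 3935 and 1360 for S over G0, and 2774 lower for S over G1, 2930 lower for G1 over cycling and 2616 lower for S over cycling, with all-gene medians of -0.24, 0.24, 0.26, -0.18, -0.21 and -0.20 in that order. The histone median of G0 over cycling was -0.35 under that fit, against 0.56. Of the ratios of the key genes and of the genes with the largest ratios, 142 were at least 2-fold, and 0 of these changed sign under the 9 alternatives run on them. This says little, since few of these settings could turn such a sign. Another floor or a pseudocount cannot, and 1 factor per array shifted ratios by less than 2-fold. The genes with the largest ratios were also chosen with all measured probe sets of the same sign. Among 47 ratios under 2-fold, 7 changed sign, in 17 values, including CCND1 for G0 over cycling (0.04, and -0.18 with the signals as deposited) and CCNA2 for S over G1 (0.21 as deposited, below 0 by under 0.005 in the main setting). In all, 1423 values stayed and 229 moved. Among list medians of the 4 main comparisons under 9 of the alternatives, 1016 stayed, 7 moved and 3 reversed, where reversed was counted only for the 58 medians outside the random range in the main setting. Of the 58 medians of these comparisons inside it, 39 changed sign under at least 1 alternative (91 values). With the signals as deposited or the 75th percentile, 1 factor per array shifts the ratios of genes above the floor alike, and changes there follow from that. For the other settings the cause was not tested. The fatty acid synthesis median of G0 over cycling was -0.0017 with the floor at the 75th percentile, against 0.58. With the 75th percentile scaling, the medians of G1 over G0 were 0.227 for oxidative phosphorylation, against -0.09, and 0.0872 for extracellular matrix, against -0.23. The median of all genes was 0.10, -0.15, 0.04, -0.07, -0.01 and 0.03 for G0 over cycling, G1 over G0, S over G1, S over G0, G1 over cycling and S over cycling, in that order. It was -0.10, -0.38, 0.23, -0.12, -0.45 and -0.22 with the signals as deposited and -0.14, 0.13, -0.05, 0.12, 0.04 and -0.02 with the 75th percentile, and list medians are best read against these. Genes near the floor have only bounds, and 4640 genes were at it on both arrays for G0 over cycling. No paired analysis was possible because each group holds 1 array, so that only replicate number 1 is shared.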

Other observations

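The tests of the ACTB and GAPDH ratios and of polyadenylated histones, the fit of loess to all probe sets, and the limit to quantile normalisation and loess in the test of scaling were chosen only after the result was seen. The list medians of proteasome, ribosomal and respiratory chain subunits lay above the range of matched random lists for S over G1, with 23 of 27, 30 of 35 and 25 of 28 members within 2-fold. Of 27 proteasome subunits, 4 were at least 2-fold higher in S than in G1 and 0 lower (median 0.47, outside the random range in 8 of 9 alternatives), with PSMD8 2.55-fold higher. Ribosomal proteins had 5 of 35 higher (median 0.21, all 9), including RPL8 (2.19-fold), and the respiratory chain 3 of 28, UQCRC1 (3.41-fold), NDUFV1 (2.29-fold) and CYC1 (2.11-fold), with a median of 0.26 in 8 of 9. Among random lists not matched on expression, the ribosomal and respiratory medians lay inside the middle 95%, at percentiles 88 and 90.7. For G0 over cycling the medians of these lists were -0.24, -0.14 and -0.02, all within the random range, and the signs of the ribosomal and respiratory medians changed with the scaling. Amino acid and ER stress genes had 6 of 26 higher in S than in G1 and 2, ASNS and VLDLR, lower (median 0.27, 6 of 9, percentile 91.5 of unmatched lists). They included the amino acid transporter chain SLC3A2 (4.83-fold) and the chaperone calreticulin, CALR (3.28-fold).

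The median of the interferon response list was lower on the cycling array than on the S and G0 arrays. Of 25 measured in S and cycling cells, 8 were at least 2-fold higher in S than in cycling cells and 0 lower (median 0.56, all 9 alternatives), including BST2 (at least 6.90-fold), ISG15 (265 against 45.6, 5.81-fold) and IRF7 (3.06-fold). In G0 8 of 25 were higher than in cycling cells and 1, IFIT1, lower (median 0.54, 8 of 9). For G1 over cycling the median was 0.35, and -0.15 with the signals as deposited. Fatty acid synthesis had 4 of 11 members higher in G0 than in cycling cells, SCD (2.77-fold), FADS2 (2.60-fold), SREBF1 (at least 2.95-fold) and ACSS2 (2.31-fold), with a median of 0.58 outside the random range in 4 of 9 alternatives, at percentile 93.7 of unmatched lists, and of -0.0017 with the floor at the 75th percentile. The p53 targets went both ways, with medians of 0.03 for G0 over cycling, whose sign changed with the scaling, and -0.34 for G1 over G0, where GADD45A was 4.44-fold higher and TP53INP1 3.73-fold lower. The DREAM list had a median of -0.58 for G0 over cycling, outside the random range in 4 of 9. Of its 10 measured members 1, LIN52, was past 2-fold, and the probe sets of LIN52 differed in sign. Cytokine genes and SRF and YAP targets had medians of -0.03 and -0.27 for G0 over cycling, and the amino acid and ER stress list -0.02, and of these the cytokine and ER stress signs changed with the scaling. The 15 key genes had a median of -1.50 for the same comparison.

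In the main setting more genes were higher than lower in G0 than in cycling cells. This turned under other settings, with a higher share of 39.8% with the 75th percentile and 25.2% with the loess fitted above the floor. A candidate explanation is that dim signals were raised on the G0 array, whose median scaled signal was 22.6. Among genes with a mean signal above the 75th percentile of all signals, 567 were higher and 873 lower, a higher share of 39.4%. The share of 47.4% (1842 higher and 2040 lower) with the signals as deposited does not decide whether scaling by the trimmed mean made the excess, since that setting lowers the ratios by 0.22 log2 before the floor, and a lower share follows from that. The scaling, after which the hybridisation controls had a mean log2 ratio of 0.30 against 0.08 as deposited, and a broad increase of many dim transcripts in quiescent cells stay open, and no biological explanation was tested.

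Glycolysis and hypoxia genes were lower on the G1 array than on the cycling array. After quantile normalisation and loess the list median stayed at least 0.879 log2 below the lower end of the middle 95% of random lists. Both settings act by signal level and, like 1 factor per array, move the list and random lists of similar expression nearly alike. The test of scaling could thus hardly turn, and shows only that the list was low against genes of similar signal. Loss of 5' sequence stays open, since the ACTB 3' to 5' ratio on the G1 array was 13.4, below the highest of the other arrays (17.6), while the GAPDH ratio of 7.01 was above the others (at most 4.47). A second list of hypoxia-induced genes that shares no member with the first had a median of -0.84 for G1 over cycling (12 of 26 at least 2-fold lower, 2 higher, percentile 0), which is consistent with the hypothesis of lower hypoxia signalling in the G1 culture than in the cycling one. This was not particular to G1, since its medians were -0.83 for S over cycling, -0.45 for G0 over cycling, -0.44 for G1 over G0 and -0.53 for S over G0, at percentiles 0, 1.72, 1.06 and 0.05. For S over G1 its median of -0.03 (percentile 41.2) did not go with that of the first list (0.29, percentile 99.7), and the first list lay at -0.31 for G0 over cycling, at percentile 28.4 of matched and 1.25 of unmatched random lists.

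The replication-dependent histone list had a median of 0.56 for G0 over cycling, with 6 of 26 members at least 2-fold higher, 0 lower and 20 within 2-fold (percentile 99.2, outside the random range in 3 of 9 alternatives and down to percentile 76.5). After loess the median was 0.31 at percentile 95.5, or -0.35 at percentile 76 with the first fit, so that raised dim signals on the G0 array may account for it. Cross-hybridisation between histone paralogs was not decided, since without shared probe sets the median of 19 members was 0.31 at percentile 76.5. The 5 genes known to give polyadenylated transcripts, H1-2, H2AC6, H2BC5, H2BC12 and H2BC21, had a median of 2.11 against 0.34 for the other 21. This decides nothing, since they were named after their values were seen and 4 of them have the 4 largest ratios of the list, and the effect of probe GC content was not analysed here.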
